A study of Mus musculus with 9 samples.

How the data were processed

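RNA was measured in 3T3-L1 cells, a mouse line of adipocyte precursors, after 24 h in an adipogenic cocktail. The cocktail held insulin (0.1 µg/mL), isobutylmethylxanthine (30 µg/mL) and dexamethasone (0.1 µg/mL). The 9 libraries, poly(A)-selected and strand-specific per the labels, formed 3 groups of 3. The MDI group received the albumin vehicle, the OA group 100 µM oleic acid bound to albumin, and the OA_T0 group the same acid with 5 µM T0901317, an agonist of the liver X receptors (LXR). No group received T0901317 without oleic acid. Nothing states whether the replicates of a group were separate cultures, so the p-values may measure technical spread only.

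The deposited values were a signal per gene: counts that were not whole numbers, which the authors divided by 1 factor per library. The submitters' notes named CASAVA 1.8.2, TopHat, HTSeq and DESeq2 and the genome build mm9, with no role or order for each tool. Low values in each library piled up on multiples of 1 step, taken as the worth of 1 fragment. Between 5 and 50 steps, 63.1% to 68.9% of the values were whole multiples within 0.05 of a step. Whole reads were therefore not recovered, and tests for read counts were not run. The deposited total divided by the step gave an estimated depth per library, and 3 fragments set the floor of detection. Such floors cover counting error only.

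Of 28965 gene symbols, 28037 were found in the GENCODE M21 annotation, which served for GC content and transcript length. No positions are given, because the notes name an older build than this annotation. Reads shared between near-identical paralogs cannot be separated in these values.

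Values were taken as log2(value + 1), and the 15002 genes with a mean deposited value of at least 10 over the 9 libraries were tested. Fold changes on this scale understate the change of genes with low values. The test was limma 3.58.1 in R 4.3.3, with an intensity trend and 1 spread shared by the 3 groups. Its two-sided p-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, and an adjusted p below 0.05 counted as passing. A gene was called non-overlapping when the 3 libraries of one group all lay beyond the 3 of the other.

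Before the data were examined, 28 gene lists were fixed, on lipid metabolism, adipogenesis, the cell cycle, stress, inflammation, other cell types and RNA quality. Of their 526 symbols, 501 were found directly, 10 through synonyms, and 15 were not analysed here. Lists were tested with camera, in limma, at a preset correlation between genes of 0.01, and again with a correlation estimated from the data and with fry. The p-values were adjusted over the lists of a comparison. Passing members were counted with p-values adjusted over all tested genes and adjusted over the list alone. Lists could share genes, and a shared gene was counted in each, so lists are not independent of one another. Among others, 4 LXR targets, 3 genes of fatty acid synthesis, 7 lipid droplet genes and 7 adipocyte markers were also on another list.

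The rule for named genes was also fixed beforehand. It took 16 fixed genes in every comparison and up to 4 passing members per list with the smallest adjusted p. It also took the 8 largest rises and 8 largest falls in OA vs MDI and in OA_T0 vs OA, and 5 of each in OA_T0 vs MDI. These had to pass the test without overlap and to average at least 50 in the higher group, and unnamed gene models were left out.

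The OA libraries enter OA vs MDI and OA_T0 vs OA with opposite signs. Correlations and covariances between comparisons were therefore set beside 100 simulated data sets with unchanged groups and independent noise in each gene and library, and overlaps beside the number that independent lists would give. The opposite calls were also counted, as a test added after the data were seen, with the OA libraries divided in 6 ways into 1 and 2, so that those set against MDI were not those set against OA_T0. A lone library is assumed there to vary like the others.

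The procedure was tested on simulated data in which 200 genes were changed by 1.5-fold, 2-fold or 4-fold. In OA vs MDI it recovered 73.1%, 92.4% and 98.4% of these, in OA_T0 vs OA 68.2%, 80.6% and 98.5%, and in OA_T0 vs MDI 75.8%, 75.4% and 95.3%. False calls made up 8.06%, 7.34% and 5.33% of the calls in the same order. A raised list of 20 genes was called in each comparison, and 0 of 20 unchanged lists were called. The simulated genes varied independently, so this does not cover false calls of lists whose genes vary together. In the real lists the estimated correlation between genes reached 0.937, for interferon response genes.

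The alternatives tried were pseudocounts of 0.5 and 5, no filter and a filter at 50, quantile normalisation, equal totals, a fit of only the groups compared, replicate number as a block, robust variance estimates, and leaving out each library. Voom on estimated fragments, removal of trends on GC content and length, and leaving out both libraries low in histone transcripts were added after the data were seen.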

Results

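The data were poly(A) RNA profiles of 3T3-L1 adipocyte precursors after 24 h in adipogenic cocktail, with vehicle (MDI), oleic acid (OA) or oleic acid and the LXR agonist T0901317 (OA_T0), each with 3 libraries. Estimated depths were 59.9, 26.3 and 25.6 M fragments for MDI, 24.4, 21.4 and 29.3 M for OA, and 28.3, 29.3 and 18.0 M for OA_T0. The floor of 3 fragments lay between 1.35 and 4.62 deposited units, so low genes were measured least precisely in OA_T0 replicate 3. Across the tested genes, log values correlated at 0.986 to 0.994 between libraries of a group and at 0.984 to 0.990 between groups; genes are not independent replicates. A ribosomal RNA gene took 0.649% of the values in OA replicate 1, 3.06% in OA_T0 replicate 3 and 4.40% to 5.96% in the others. The histone list, a sign of RNA selection, stood at -1.11 in both of those libraries, as the mean log2 difference from MDI. Group values below are means of deposited normalised counts ± SD with n = 3.

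The comparison of OA with MDI asks what oleic acid adds to the cocktail. Most genes of the fatty acid oxidation list and some of lipid storage rose, and most genes of the ATF4 amino acid stress response fell. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 12.1-fold, from 1014 ± 106 to 12291 ± 1310.3. Cpt1a, which admits fatty acids to mitochondria, rose 4.55-fold, from 1321 ± 120.0 to 5993 ± 143. Plin2, a coat protein of lipid droplets, rose 3.97-fold, from 1430.1 ± 152 to 5673 ± 412.

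Of 23 tested members of the list of PPAR targets and fatty acid oxidation, 16 rose, 1 fell and 6 did not pass; 18 rose and 1 fell when adjusted over the list alone. The list had adjusted p = 1.42e-27 by camera and adjusted p = 0.0715 with an estimated correlation, with a median log2 fold change 0.50. The member that fell was Acot2, a mitochondrial acyl-CoA thioesterase, at a log2 fold change of -0.38 (adjusted p = 0.0467), and the members lower numbered 0 without MDI replicate 1, MDI replicate 2, MDI replicate 3, OA replicate 1 or OA replicate 3. Pdk4, a brake on glucose oxidation, rose by a log2 fold change of 1.18 (SE 0.06, adjusted p = 5.95e-09).

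Among adipocyte markers, 4 of 11 rose and 0 fell (6 and 0 adjusted over the list alone). Fabp4, a fatty acid carrier, rose from 374 ± 81.4 to 2024 ± 312, Cd36, a fatty acid transporter, from 20.3 ± 5.11 to 321 ± 65.0, and Lpl, lipoprotein lipase, from 5424 ± 197 to 9358 ± 183. These genes together had adjusted p = 5.10e-08 by camera and adjusted p = 0.242 with an estimated correlation. Of 15 lipid droplet and triglyceride genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone). They included Plin4, another droplet coat protein (log2 fold change 1.16), and Lipe, hormone-sensitive lipase (1.52). Lipe was also counted among the adipocyte markers, and Plin2 in both the droplet and the PPAR list. The droplet list had adjusted p = 5.94e-05 by camera and adjusted p = 0.289 with an estimated correlation. Pparg, the master regulator of adipogenesis, averaged 945 ± 12.8 in MDI and 964 ± 44.4 in OA (adjusted p = 0.848), and Cebpa 383 ± 94.1 and 455 ± 47.5 (adjusted p = 0.413). Outside the lists, Trarg1, which acts in glucose transporter traffic, and Acsbg1, an acyl-CoA synthetase, were among the largest rises.

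Of 19 genes of the ATF4 stress response, 0 rose, 15 fell and 4 did not pass (0 and 16 adjusted over the list alone), with a median log2 fold change -0.43. As a list these genes had adjusted p = 4.52e-20 by camera and adjusted p = 0.141 with an estimated correlation. Trib3, a pseudokinase that binds AKT, fell from 3181 ± 50.6 to 1698 ± 44.6, Cth, an enzyme of cysteine synthesis, from 1634 ± 68.1 to 915 ± 28.4, and Slc7a5, an amino acid transporter, from 7917 ± 398 to 5021 ± 57.9. Some immediate early genes, fixed as a sign of sample handling, fell as well: 0 of 12 rose and 5 fell (0 and 9 adjusted over the list alone). Among those that fell was Atf3, which is also on the ATF4 list. The early gene list had adjusted p = 6.40e-07 by camera and adjusted p = 0.0715 with an estimated correlation. The early genes lower numbered 2 without OA replicate 1 or OA replicate 2 and 3 without MDI replicate 1 or MDI replicate 2. Egr1 fell by a log2 fold change of 0.40 and Myc by 0.33.

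Of 30 genes of G2 and M phase, 13 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change 0.25. The set test gave adjusted p = 6.68e-14 by camera and adjusted p = 0.363 with an estimated correlation. Fewer of them passed with 1 library left out: 1 without MDI replicate 1 or MDI replicate 2, 3 without OA replicate 1, 7 without OA replicate 3 and 8 without OA replicate 2. Cenpf, a kinetochore protein, rose from 4370.3 ± 214 to 5982 ± 503, while the proliferation marker Mki67 had adjusted p = 0.0503 and passed without OA replicate 3 (0.0334). Of 30 S phase genes, 1 fell and 0 rose under both adjustments, with a median log2 fold change -0.16. That list had adjusted p = 6.21e-08 by camera and adjusted p = 0.400 with an estimated correlation. The gene that fell was Cdc6, a replication licensing factor (log2 fold change -0.45), and its call was lost without MDI replicate 1 (adjusted p = 0.0961), MDI replicate 2 (0.133), OA replicate 1 (0.0891), OA replicate 2 (0.0691) or OA replicate 3 (0.0662). The S phase genes lower numbered 0 without MDI replicate 1, MDI replicate 2, OA replicate 1 or OA replicate 2, 3 without OA_T0 replicate 3 and 6 without OA_T0 replicate 2.

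Of 19 genes on TGF-beta and smooth muscle, 0 rose and 5 fell under both adjustments. The list had adjusted p = 0.00351 by camera and adjusted p = 0.389 with an estimated correlation. Ccn2, a matrix protein induced by TGF-beta, fell from 189 ± 47.5 to 59.8 ± 8.09, and Acta2, smooth muscle actin, from 3693 ± 605 to 1939 ± 167. Id4, an inhibitor of helix-loop-helix factors, Ankrd1 and Megf10 were also among the largest falls. Cholesterol synthesis and uptake showed 0 of 25 higher and 2 lower under both adjustments. These genes together had adjusted p = 0.00488 by camera and adjusted p = 0.634 with an estimated correlation, and without MDI replicate 3 adjusted p = 0.247 by camera. Their lower members numbered 0 without MDI replicate 2, MDI replicate 3, OA replicate 1 or OA replicate 2 and 1 without OA replicate 3 or OA_T0 replicate 1. The NF-kB and chemokine list had 2 of 21 higher and 5 lower (3 and 5 adjusted over the list alone). It had adjusted p = 0.0384 by camera and adjusted p = 0.389 with an estimated correlation, and its call was lost without MDI replicate 1 (0.0554), MDI replicate 3 (0.0533) or OA replicate 2 (0.168). NF-kB members higher numbered 1 without MDI replicate 1 or MDI replicate 2, and those lower 2 without MDI replicate 2 and 3 without MDI replicate 1, OA replicate 2 or OA replicate 3. Of 13 LXR targets 2 rose, Lpcat3 and Tmem86a, and 1 fell, Scd2 (2 and 2 adjusted over the list alone), and the list had camera adjusted p = 0.488. The calls of Scd2 and Tmem86a were lost without several single libraries, up to adjusted p = 0.161 without MDI replicate 2 for Scd2 and 0.124 without MDI replicate 1 for Tmem86a. The LXR targets higher numbered 1 without MDI replicate 1, MDI replicate 2, OA replicate 1 or OA replicate 3, and those lower 0 without MDI replicate 2, MDI replicate 3, OA replicate 1, OA replicate 2, OA replicate 3 or OA_T0 replicate 1. Fatty acid synthesis had 1 of 18 higher, Fasn, and 2 lower, Mid1ip1 and Scd2 (1 and 3 adjusted over the list alone), with camera adjusted p = 0.113. That list passed without MDI replicate 1 (0.0334), and Fasn did not pass without MDI replicate 2 (0.0501). Its lower members numbered 1 without MDI replicate 2, MDI replicate 3, OA replicate 1, OA replicate 2 or OA_T0 replicate 1. In the interferon list 0 of 22 rose and 3 fell (0 and 20 adjusted over the list alone), with a median log2 fold change -1.07. It had adjusted p = 2.97e-12 by camera and adjusted p = 0.389 with an estimated correlation. That count depended on single libraries, also of OA_T0, whose spread enters the pooled test: it was 0 without MDI replicate 1 or MDI replicate 2, 1 without OA replicate 2 or OA replicate 3, 5 without MDI replicate 3, 8 without OA replicate 1, 18 without OA_T0 replicate 2 and 20 without OA_T0 replicate 3.

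In all, limma called 514 genes higher and 504 lower in OA than in MDI, 43 and 27 of them by at least 2-fold; 1009 of the 1018 did not overlap between groups. Over all tested genes 26.1% did not overlap, where chance gives 10%. Leaving out 1 library took the higher count to 220 (MDI replicate 1), 211 (MDI replicate 2), 279 (OA replicate 1) or 324 (OA replicate 3). It took the lower count to 300 (MDI replicate 1), 155 (MDI replicate 2), 287 (OA replicate 1) or 317 (OA replicate 2).

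The comparison of OA_T0 with OA asks what the LXR agonist changes in cells given oleic acid. Some known LXR targets and most genes of cholesterol and fatty acid synthesis rose, and most genes of the fatty acid oxidation list fell. Abca1, a cholesterol exporter, rose 6.67-fold, from 1101 ± 94.3 to 7341 ± 382. Scd2, a fatty acid desaturase, rose 3.68-fold, from 14460.0 ± 232 to 53525 ± 6479.7. Angptl4 was 12.9-fold lower, at 949 ± 43.9.

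**Figure D1:**
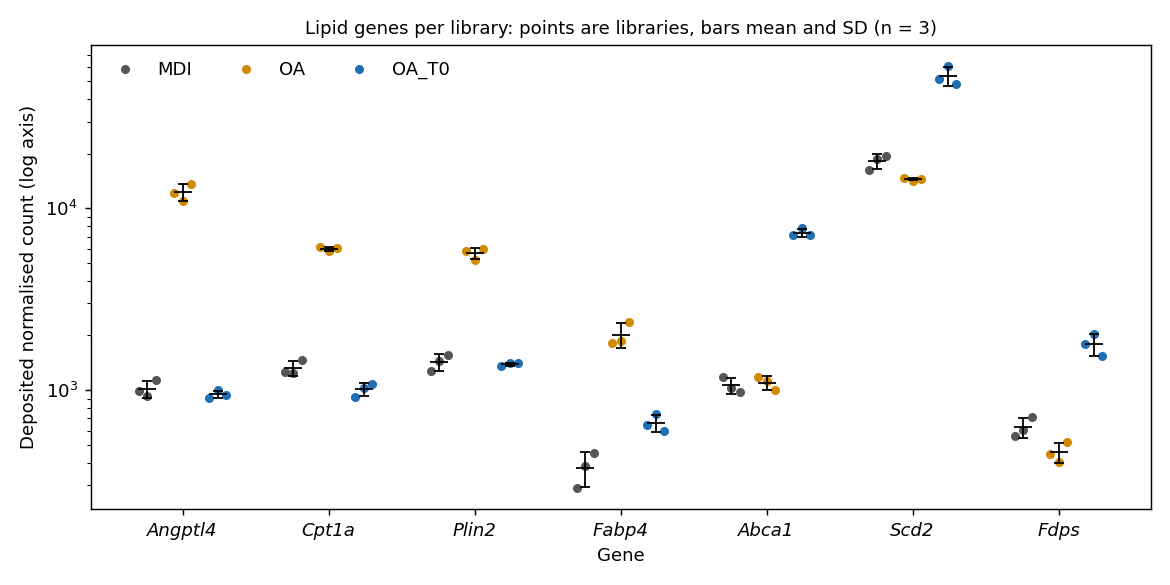
Deposited normalised counts (log axis) of 7 lipid genes in each library of MDI, OA and OA_T0; points are libraries and bars the mean and SD, n = 3. Angptl4, Cpt1a, Plin2 and Fabp4 were highest in OA, and Abca1, Scd2 and Fdps in OA_T0.

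Of 13 LXR targets, 4 rose and 0 fell (6 and 1 adjusted over the list alone). As a list these genes had adjusted p = 4.97e-05 by camera and adjusted p = 0.266 with an estimated correlation. Beside Abca1 and Scd2 those that rose were Mylip, a ubiquitin ligase (430.0 ± 25.7 to 1378 ± 124), and Scd1, another desaturase (2731 ± 19.4 to 5527 ± 412). Scd1 and Scd2 were also counted among the genes of fatty acid synthesis. Abcg1, a sterol exporter, averaged 5.33 ± 3.18 and 18.3 ± 7.54, with adjusted p = 0.0730, and passed without OA_T0 replicate 2 (adjusted p = 0.0465). Its values in OA replicate 2 (4.03) and OA replicate 3 (3.01) lay at the floor of 3 fragments. LXR targets lower numbered 1 without OA_T0 replicate 2. The LXR genes Nr1h3 and Nr1h2 and the lipogenic factor Srebf1 did not pass in any comparison, Srebf1 averaging 882 ± 102 in MDI, 859 ± 109 in OA and 868 ± 63.2 in OA_T0.

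Cholesterol synthesis and uptake moved as a group: 24 of 25 genes rose and 0 fell under both adjustments, with a median log2 fold change 1.15. The set test gave adjusted p = 8.75e-32 by camera and adjusted p = 0.107 with an estimated correlation. Fdps, which makes farnesyl pyrophosphate, rose from 455 ± 58.0 to 1796 ± 247, and Msmo1, a sterol oxidase, from 866 ± 38.4 to 3392 ± 649. Of 18 genes of fatty acid synthesis, 14 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 fold change 0.54. The list had adjusted p = 1.41e-19 by camera and adjusted p = 0.0985 with an estimated correlation. Fads2, a desaturase, had a log2 fold change of 1.22 and Acsl3, an acyl-CoA synthetase, of 1.20. Fasn, fatty acid synthase, averaged 10558 ± 843 in OA and 12540.0 ± 1906 in OA_T0 (adjusted p = 0.0881), and passed without OA replicate 3 (0.0448) or OA_T0 replicate 3 (0.0137).

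Of the PPAR and oxidation list, 1 rose, 16 fell and 6 did not pass (1 and 19 adjusted over the list alone), with a median log2 fold change -0.52. These genes together had adjusted p = 1.41e-19 by camera and adjusted p = 0.102 with an estimated correlation. Cpt1a was 5.94-fold lower in OA_T0, at 1010.5 ± 82.9, and Plin2 4.08-fold lower, at 1386 ± 31.4. Adipocyte markers showed 1 of 11 higher and 3 lower under both adjustments. The markers had adjusted p = 0.0180 by camera and adjusted p = 0.530 with an estimated correlation. Lipid droplet genes showed 1 of 15 higher and 3 lower (1 and 4 adjusted over the list alone), and adjusted p = 0.0134 by camera and adjusted p = 0.502 with an estimated correlation. The droplet genes higher numbered 0 without MDI replicate 1, MDI replicate 2, OA replicate 2, OA replicate 3, OA_T0 replicate 1 or OA_T0 replicate 3. Without OA replicate 3 both list calls were lost, at adjusted p = 0.0991 and 0.0646 by camera. Fabp4 and Cd36 fell while Pparg rose from 964 ± 44.4 to 1185 ± 37.7.

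Of the ATF4 list, 17 of 19 rose and 0 fell (18 and 1 adjusted over the list alone), with a median log2 fold change 0.64. As a list these genes had adjusted p = 1.80e-20 by camera and adjusted p = 0.102 with an estimated correlation, and the lower members numbered 1 without OA replicate 3. Cth, Slc7a5 and Trib3 reached 1975 ± 267, 9164 ± 731 and 3668 ± 633. Immediate early genes again moved with it: 9 of 12 rose and 0 fell (10 and 0 adjusted over the list alone). Among those that rose was Atf3 (log2 fold change 1.13), which is on both lists. The early genes had adjusted p = 3.31e-06 by camera and adjusted p = 0.0985 with an estimated correlation. On TGF-beta and smooth muscle, 9 of 19 rose and 2 fell under both adjustments, among them Acta2 (log2 fold change 1.28). The set test gave adjusted p = 7.59e-04 by camera and adjusted p = 0.327 with an estimated correlation. Its higher members numbered 5 without OA replicate 1 or OA_T0 replicate 1, and the lower 1 without OA replicate 2 or OA_T0 replicate 1.

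In G2 and M phase 0 of 30 rose and 11 fell (0 and 13 adjusted over the list alone). The list had adjusted p = 6.31e-07 by camera and adjusted p = 0.502 with an estimated correlation, and its lower members numbered 2 without OA replicate 1, OA_T0 replicate 1 or OA_T0 replicate 3, 4 without OA replicate 2, 6 without MDI replicate 2 and 19 without OA_T0 replicate 2. In S phase 4 of 30 rose and 0 fell under both adjustments, and the list had adjusted p = 4.17e-05 by camera and adjusted p = 0.530 with an estimated correlation. Its higher members numbered 1 without OA_T0 replicate 1, 2 without MDI replicate 2, OA replicate 1, OA replicate 2 or OA_T0 replicate 3, 7 without OA replicate 3 and 18 without OA_T0 replicate 2. The NRF2 antioxidant list had 6 of 20 higher, among them Hmox1, heme oxygenase, and 1 lower, Cat, catalase (6 and 2 adjusted over the list alone). It had adjusted p = 0.0134 by camera and adjusted p = 0.502 with an estimated correlation, and its higher members numbered 3 without OA_T0 replicate 1. The glucocorticoid and cAMP list had 7 of 20 higher, such as Sgk1 and Nr4a1, and 3 lower under both adjustments. It had adjusted p = 0.0470 by camera and adjusted p = 0.510 with an estimated correlation, and was not called without OA replicate 2 (0.0674), OA replicate 3 (0.0601), OA_T0 replicate 1 (0.0886) or OA_T0 replicate 2 (0.108). Higher members there numbered 3 without OA replicate 2 and 4 without OA_T0 replicate 1, and lower members 0 without OA replicate 1, OA_T0 replicate 1 or OA_T0 replicate 3 and 1 without MDI replicate 2, OA replicate 2 or OA replicate 3. The interferon list had 0 of 22 higher and 1 lower, Gbp2, under both adjustments, and adjusted p = 0.00281 by camera and adjusted p = 0.628 with an estimated correlation. That list was not called without OA replicate 1 (0.145) or OA_T0 replicate 2 (0.522), and the call of Gbp2 was lost without OA replicate 1 (0.0814) or OA_T0 replicate 1 (0.0647). The interferon members lower numbered 0 without OA replicate 1 or OA_T0 replicate 1 and 18 without OA_T0 replicate 3, and 11 without both libraries low in histone transcripts, so the count of 1 depended on single libraries.

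**Figure D2:**
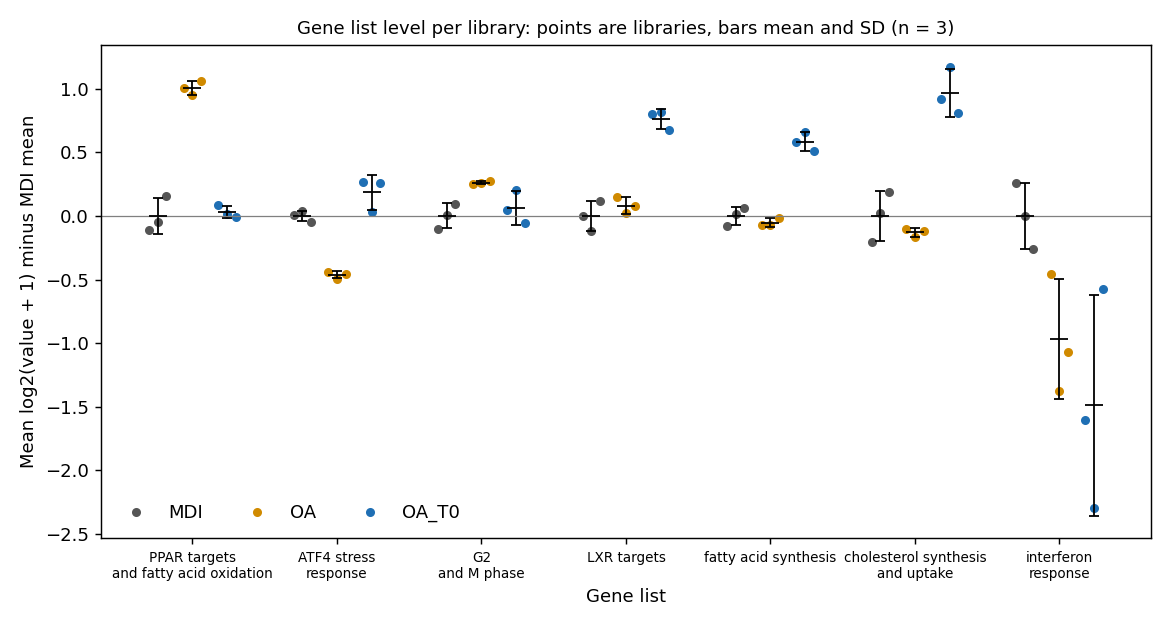
Mean log2(value + 1) of each gene list per library, minus the MDI mean; points are libraries and bars the mean and SD, n = 3. The PPAR list was high in all 3 OA libraries, the cholesterol list in all 3 OA_T0 libraries, and the interferon list ranged from -2.30 to -0.57 within OA_T0.

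In all, limma called 1240 genes higher and 1026 lower in OA_T0 than in OA, 75 and 106 of them by at least 2-fold; 2220 did not overlap, and 32.1% of all tested genes did not, where chance gives 10%. Leaving out 1 library took the higher count to 684 (OA replicate 1), 757 (OA replicate 2) or 580 (OA_T0 replicate 1). It took the lower count to 526 (OA replicate 1), 635 (OA replicate 2) or 474 (OA_T0 replicate 1).

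Many genes moved by oleic acid moved back in OA_T0. An effect of the agonist cannot be told apart here from oleic acid missing or inactive in those cultures. Of the 514 genes higher in OA, 345 were lower again in OA_T0 (67.1%), and of the 504 lower in OA, 393 were higher again (78.0%). All 16 genes of the PPAR list that rose with oleic acid fell with the agonist, to a median log2 difference from MDI of 0.01 (interquartile range -0.04 to 0.13). All 43 genes raised at least 2-fold moved back, and 17 of the 27 lowered at least 2-fold. The 738 opposite calls compare with 76.8 for independent lists, a number that leaves out the effect of sharing the OA libraries. With the OA libraries divided so that the comparisons shared none, 139 to 355 genes were called in both, and 97.2% to 100% of these moved opposite ways. The genes moving opposite ways made up 41.8% to 88.0% of the genes called in OA vs MDI there, under 50% in 3 of the 6 divisions. Only 2 genes moved the same way, Gbp4 and Gbp7, interferon-induced GTPases that were both lower and were named after their values were seen; independent lists would give 77.0. Across genes, the fold changes of both comparisons had r = -0.559 and rho = -0.571. In the simulations the shared OA libraries alone produce a negative value. There r averaged -0.500 (range -0.5356 to -0.4687) and rho -0.453 (range -0.4749 to -0.4305). With none shared r was -0.126 to -0.388.

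**Figure D3:**
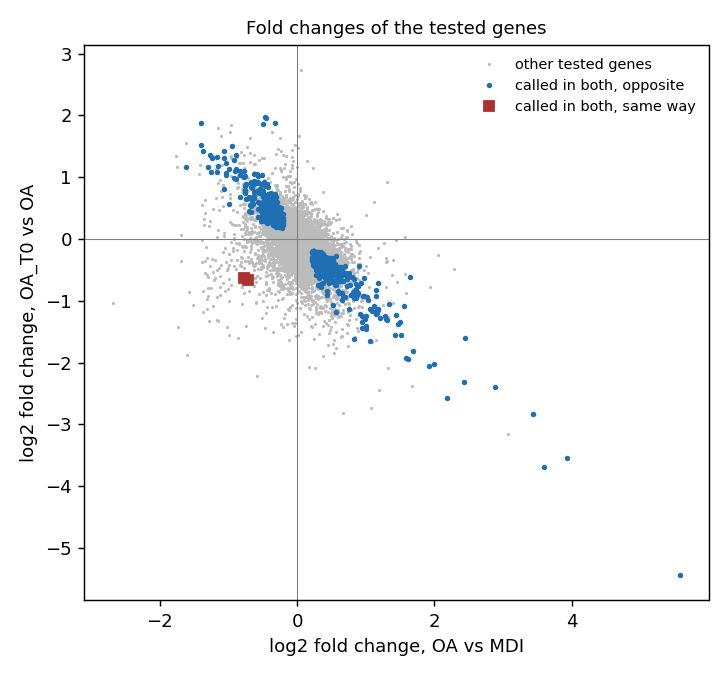
Log2 fold changes of OA vs MDI (horizontal axis) and OA_T0 vs OA (vertical axis) for the tested genes, 1 point per gene. The 738 genes called in opposite ways and the 2 called the same way are marked; sharing the OA libraries tilts the whole cloud downwards.

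Leaving out 1 library took the opposite calls to 457 (MDI replicate 1), 320 (MDI replicate 2) or 398 (OA replicate 1). The same-way calls came to 64 without OA_T0 replicate 3, 62 of them lower and 17 of them on the interferon list, to 4 without MDI replicate 3, to 1 without OA replicate 3 and to 0 without any other library.

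The comparison of OA_T0 with MDI shows the combined treatment against the vehicle. Most genes of cholesterol and fatty acid synthesis and some LXR targets were higher, and most genes of the interferon list were lower. Abca1 was 6.93-fold higher, and Mylip 3.25-fold. Scd2 rose from 18100.0 ± 1716 to 53525 ± 6479.7. Of the interferon list, 18 of 22 fell.

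Cholesterol synthesis and uptake had 22 of 25 genes higher and 0 lower (24 and 0 adjusted over the list alone), with a median log2 fold change 0.96. These genes together had adjusted p = 6.63e-43 by camera and adjusted p = 0.0977 with an estimated correlation. Idi1, an isomerase of the pathway, rose from 831 ± 142 to 2338 ± 462. Fatty acid synthesis had 15 of 18 higher and 0 lower (17 and 0 adjusted over the list alone), and adjusted p = 1.62e-29 by camera and adjusted p = 0.0703 with an estimated correlation. Fasn rose from 7737 ± 380.2 to 12540.0 ± 1906. LXR targets had 5 of 13 higher and 0 lower under both adjustments, and adjusted p = 8.30e-11 by camera and adjusted p = 0.0977 with an estimated correlation. In the PPAR and oxidation list 0 of 23 rose and 1 fell under both adjustments, and it had adjusted p = 0.736 by camera and adjusted p = 0.902 with an estimated correlation. The gene that fell was Cpt1a (log2 fold change -0.39), which did not pass without OA_T0 replicate 1 (adjusted p = 0.103). Adipocyte markers had 4 of 11 higher and 0 lower under both adjustments, with Lpl at 8651 ± 266 and Fabp4 at 661 ± 72.9, and adjusted p = 4.20e-04 by camera and adjusted p = 0.488 with an estimated correlation. The markers higher numbered 2 without MDI replicate 1, MDI replicate 2 or OA_T0 replicate 1. ATF4 genes had 3 of 19 higher and 0 lower (11 and 0 adjusted over the list alone), and adjusted p = 5.41e-07 by camera and adjusted p = 0.488 with an estimated correlation. The ATF4 genes higher numbered 0 without MDI replicate 1, MDI replicate 2 or OA_T0 replicate 1, 1 without OA_T0 replicate 3 and 10 without OA_T0 replicate 2.

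G2 and M phase had 0 of 30 genes passing and camera adjusted p = 0.103, and passed without MDI replicate 3 (0.0114) or OA_T0 replicate 3 (5.20e-04). Extracellular matrix had camera adjusted p = 0.0620 and passed without MDI replicate 1 (0.0405), MDI replicate 2 (0.0461), OA_T0 replicate 1 (0.0428) or OA_T0 replicate 2 (0.0142). The glucocorticoid and cAMP list had camera adjusted p = 0.0572 and passed without MDI replicate 1 (0.00193), OA replicate 1 (0.0477) or OA_T0 replicate 3 (0.0102). The NF-kB list had camera adjusted p = 0.0572 and passed without OA_T0 replicate 1 (0.0415) or OA_T0 replicate 3 (0.0127). S phase had 0 of 30 passing and camera adjusted p = 0.727, and passed, pointing up, without OA_T0 replicate 2 (0.00455).

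The interferon list had 0 of 22 higher and 18 lower (0 and 21 adjusted over the list alone), with a median log2 fold change -1.60. It had adjusted p = 3.02e-25 by camera and adjusted p = 0.286 with an estimated correlation. Ifih1, a sensor of viral RNA, fell from 621 ± 31.5 to 273 ± 97.2, and Gbp2, an interferon-induced GTPase, from 661 ± 47.7 to 289 ± 119. Tgtp2, a GTPase with the near-identical neighbour Tgtp1, fell from 249 ± 53.2 to 52.2 ± 30.0. The list scores spread widely within OA_T0, at -1.60, -2.30 and -0.57, where OA had -0.46, -1.38 and -1.07 and MDI 0.26, 0.00 and -0.26. The highest OA_T0 score was in replicate 3 and the highest OA score in replicate 1, the libraries low in histone transcripts. The passing members numbered 2 without MDI replicate 1, 3 without MDI replicate 2, 2 without OA_T0 replicate 1 and 10 without OA_T0 replicate 2. Without the filter on low values Ifih1, Gbp2 and Tgtp2 did not pass, at adjusted p = 0.0609, 0.0800 and 0.0920.

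In all, limma called 188 genes higher and 204 lower in OA_T0 than in MDI, 23 and 72 of them by at least 2-fold; 390 did not overlap, and 23.5% of all tested genes did not, where chance gives 10%. Leaving out 1 library took the higher count to 68 (MDI replicate 1), 70 (MDI replicate 2), 284 (MDI replicate 3) or 66 (OA_T0 replicate 1). It took the lower count to 61 (MDI replicate 1), 52 (MDI replicate 2) or 44 (OA_T0 replicate 1).

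Further lists did not pass in OA vs MDI: adipogenic transcription factors had camera adjusted p = 0.319, preadipocyte genes camera adjusted p = 0.0542, extracellular matrix camera adjusted p = 0.181, endoplasmic reticulum chaperones camera adjusted p = 0.291, circadian clock camera adjusted p = 0.611 and brown and beige adipocyte genes camera adjusted p = 0.488. Camera asks for a shared direction, and with all libraries members of some of these lists passed both ways. Of 30 extracellular matrix genes 2 rose and 7 fell, and of 18 adipogenic transcription factors 4 rose and 2 fell. Over all tested genes 6.79% were called. In OA_T0 vs OA, where 15.1% of all tested genes were called, 8 matrix genes rose and 6 fell. Of the adipogenic factors 5 rose and 6 fell there. The NRF2 list had camera adjusted p = 0.113 in OA vs MDI and passed without OA replicate 3 (0.0233). The preadipocyte list passed without MDI replicate 1 (0.0334), MDI replicate 2 (0.0326) or OA replicate 3 (0.0182). Markers of other cell types did not pass as lists in any comparison. In OA vs MDI macrophage and leukocyte markers had camera adjusted p = 0.754, endothelial markers camera adjusted p = 0.278, and muscle and bone markers camera adjusted p = 0.0773, the last passing without MDI replicate 1 (0.0432). Of epithelial markers only Krt19 was tested, a keratin that averaged 14.9 ± 5.97 in OA and 3.07 ± 0.0456 in OA_T0, where each library lay at or below its floor of 3 fragments. It passed in OA_T0 vs OA (adjusted p = 0.0272), and did not without OA replicate 1 (0.134), OA replicate 3 (0.0544) or OA_T0 replicate 1 (0.0743). Histone genes had camera adjusted p = 0.0806 in OA vs MDI, passing without OA replicate 2 (0.0447) or OA_T0 replicate 3 (0.0469). Akt2, an insulin signalling kinase, averaged 2668 ± 151 in MDI, 2799 ± 224 in OA and 2847 ± 163 in OA_T0 and passed in no comparison, and the insulin receptor to AKT list had camera adjusted p = 0.319, camera adjusted p = 0.554 and camera adjusted p = 0.0795 in OA vs MDI, OA_T0 vs OA and OA_T0 vs MDI. Of its 24 genes 0 rose and 4 fell in OA vs MDI, and 4 rose and 4 fell in OA_T0 vs OA. Trib3, Irs1, Igf1r and Pik3cb fell in OA vs MDI and rose in OA_T0 vs OA. For Irs1, Igf1r and Pik3cb the log2 fold changes were -0.39, -0.29 and -0.34, then 0.41, 0.26 and 0.43. In OA_T0 vs MDI 0 rose and 1 fell. Median and mean differed in sign, with no call by camera, for the insulin receptor to AKT list in OA vs MDI and OA_T0 vs OA, and for extracellular matrix and circadian clock in OA vs MDI. They also did so for muscle and bone markers and histone genes in OA_T0 vs OA and for S phase and preadipocyte genes in OA_T0 vs MDI, and the NF-kB list in OA_T0 vs OA had both below 0 and a test pointing up. No list called at the preset correlation passed with an estimated correlation.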

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

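Voom on estimated fragments, the removal of trends on GC content and length, and leaving out both libraries low in histone transcripts (OA replicate 1 and OA_T0 replicate 3) were tests chosen only after the results were seen. Each count stayed within 1.5 times its value under pseudocounts of 0.5 and 5, a filter at 50 and a fit of only the groups compared. With no filter, 27045 genes were tested, and the calls were 233 higher and 234 lower in OA vs MDI, 620 lower in OA_T0 vs OA, 72 higher and 38 lower in OA_T0 vs MDI, 379 opposite and 0 the same way. More low and noisy genes enter there by construction. Robust variance estimates gave 132 lower in OA_T0 vs MDI and 0 the same way, and quantile normalisation and equal totals each gave 1 the same way; the cause was not tested. Voom gave 4 the same way. With GC and length trends removed, 822 were higher and 837 lower in OA vs MDI and 1183 opposite; the cause was not tested. Without both histone-low libraries, OA_T0 vs OA had 524 higher and 402 lower, with 376 opposite, 40 the same way and r = -0.490, from fewer libraries. With 1 library left out, OA vs MDI ranged over 211 to 658 higher and 155 to 639 lower, OA_T0 vs OA over 580 to 1443 and 474 to 1239, and OA_T0 vs MDI over 66 to 284 and 44 to 247. Opposite calls ranged over 320 to 886, same-way calls over 0 to 64, and r over -0.622 to -0.457. The simulations were not repeated with 1 library left out, so these values of r have no matching reference. Calls of lists ranged over 30 to 36 and of named genes over 164 to 202. With an estimated correlation between genes 0 lists were called, against 24 with fry and 31 by camera at the preset correlation. Fry lost 12 camera calls, among them interferon in OA_T0 vs MDI (fry adjusted p = 0.0669) and cholesterol in OA vs MDI (0.429). It also lost G2 and M phase and S phase in OA vs MDI (0.0519 and 0.179) and in OA_T0 vs OA (0.075 and 0.128). Fry gained 5, such as circadian clock (0.0109) and brown and beige genes (0.00525) in OA_T0 vs OA. The list OA_T0 vs MDI S phase turned from down to up without OA_T0 replicate 2, at adjusted p = 0.00455; with 1 library left out its values ranged up to 0.905, and under the other settings from 0.0628 to 0.997. The cause of that turn was not tested. Equal replicate numbers showed no common pairing, with 1 of 9 same-number pairs correlated above 0.1, over a range of -0.256 to 0.259. With 3 libraries per group this cannot exclude a pairing. The second axis of a principal component analysis held 21.3% of the variance, against 26.1% on the first, and crossed the groups. MDI replicate 1, MDI replicate 2 and OA_T0 replicate 3 stood at 17.8 to 22.3. At the other end were OA replicate 3 (-21.5) and OA_T0 replicate 2 (-19.3). The cause was not tested. With replicate number as a block, the calls were 433 and 417, 1095 and 916, and 156 and 183, with 605 opposite and 2 the same way. Over all settings, single-gene results kept their side of the threshold 4577 times, lost the call 396 times, gained it 11 times and reversed 0 times. Lists did so 1568, 60, 63 and 1 times. No scaling moved the median of all genes by more than 0.1 on the log2 scale. Tests for whole read counts, planned for the case that whole reads could be recovered, were not run. Depth limits low genes most in OA_T0 replicate 3, where 3 fragments correspond to 4.62 units.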

Other observations

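The division of the OA libraries, the removal of GC and length trends, the oleic acid supply, the size of the interferon fall and the differences between cultures were tests chosen only after the results were seen; the splits and the count without a single library were written before.

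Some genes were higher than in MDI both in OA and in OA_T0, and without a group on the agonist alone a kept response to oleic acid and an effect of the agonist were not separated. Aldh1a7, an aldehyde dehydrogenase singled out after its values were seen, averaged 473 ± 94.9 in MDI, 1469 ± 168 in OA and 957 ± 118 in OA_T0, and passed limma's test against MDI in both groups. Lpl, lipoprotein lipase, averaged 5424, 9358 and 8651 in the same order, and Lpcat3, a phospholipid acyltransferase and LXR target, 1497, 2486 and 2738. In OA vs MDI, Lpcat3 had a log2 fold change of 0.73 (SE 0.07, adjusted p = 5.93e-06).

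Single genes of sugar use and of the precursor state moved in both directions with oleic acid, within lists that did not pass. Hk2, a hexokinase, averaged 1379.8 ± 138 in MDI, 849 ± 5.79 in OA and 1375 ± 175 in OA_T0, and fell with oleic acid and rose with the agonist. Slc2a1, a glucose transporter, followed the same course, with log2 fold changes of -0.32 and 0.44. Bnip3, a mitophagy receptor, and Pdk1, a brake on glucose oxidation, went the other way, at 0.35 and 0.34 with oleic acid and -0.51 and -0.32 with the agonist. Bnip3 did not pass in OA vs MDI without MDI replicate 1 (0.0586). Over the glycolysis list 2 of 19 rose and 2 fell in OA vs MDI (6 and 3 adjusted over the list alone). In OA_T0 vs OA 2 rose and 3 fell (2 and 5 adjusted over the list alone). With p-values adjusted over all tested genes, the rises in OA vs MDI numbered 1 without MDI replicate 1 and 4 without MDI replicate 3. The falls in OA_T0 vs OA numbered 5 without OA_T0 replicate 2. The list pointed up in OA vs MDI, with 15 of 19 members above 0 and camera adjusted p = 0.0564, and down in OA_T0 vs OA, with 4 above 0 and camera adjusted p = 0.0549. It passed, pointing up, in OA vs MDI without MDI replicate 2 (0.0477), MDI replicate 3 (0.0435), OA replicate 1 (0.0174), OA replicate 2 (0.0167) or OA_T0 replicate 3 (0.0498). In OA_T0 vs OA it passed, pointing down, without MDI replicate 1 (0.0342), OA replicate 1 (0.0197), OA replicate 2 (0.0116) or OA_T0 replicate 1 (0.0472). Of 17 precursor genes 1 rose and 5 fell with oleic acid (2 and 7 adjusted over the list alone). The lower members adjusted over all tested genes numbered 2 without MDI replicate 2. Runx1, a transcription factor, fell with oleic acid (-0.75) and Pdgfra, a receptor of adipocyte precursors, rose (0.47). Both turned back with the agonist, at 0.65 and -0.65.

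The first pattern weighed is the 738 genes called opposite ways. Over 100 regroupings of the 9 libraries, 1, the real one, gave as many. The highest other gave 463, in a regrouping that kept the 3 OA libraries together. Most of the others mixed libraries of different groups, which puts treatment differences into the spread, and gave 0 opposite calls. The regroupings therefore cannot exclude chance differences between cultures. With the OA libraries divided in 6 ways so that the comparisons shared none, 139 to 355 genes were called in both, at least 97.2% of them opposite ways (41.8% to 88.0% of those called in OA vs MDI), where noise in shared libraries needs about as many the same way, but anything else common to the 3 OA cultures would not be caught there and stays open. Removing trends on GC content and length left 1183 opposite calls. Had those trends been the cause, a fall to the highest simulated number, 1, was predicted, and otherwise a count within 1.5 times of 738. Both bounds were set before that count was known, and it met neither. The calls did not fall without those trends, but by its own rule the test does not decide. Oleic acid missing or inactive in the OA_T0 cultures cannot be told apart from an effect of the agonist. The 16 genes of the PPAR and oxidation list raised by oleic acid stood at a median log2 difference of 0.0103 from MDI. No group received the agonist alone. The fold changes of OA vs MDI and OA_T0 vs MDI had a covariance of 0.0272, above the 0.0178 to 0.0222 simulated with unchanged groups. Their r was 0.317, below the simulated 0.467 to 0.532. Of the genes called in both, 55 moved the same way and 35 opposite ways. Independent lists give 13.3 of each, a number that leaves out the shared MDI libraries, which favour the same way. The agonist could move the same genes by itself, and that it counters the oleic acid response may be held only as a hypothesis.

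The second pattern weighed is the fall of interferon genes in OA_T0 against MDI. Leaving out 1 library took the 18 passing members to as few as 2, which by the rule written before fits a call that hangs on a single library, yet omitting MDI replicate 1, MDI replicate 2 or OA_T0 replicate 1 gave 2, 3 and 2 members and also took the lower calls of the whole comparison from 204 to 61, 52 and 44. A second test, added after that outcome was known and not replacing it, found the median log2 fold change nearest to 0 at -1.01, without OA_T0 replicate 2, against -1.60 with all libraries, so no single library accounted for most of the fall. The gap between the nearest MDI and OA_T0 libraries was 0.314 in list score, against a range of 1.73 within OA_T0, so differences between cultures unrelated to treatment cannot be told apart from a treatment effect. An effect of treatment on interferon genes may be held only as a hypothesis.

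For the counts of genes, the splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes: 1018 in OA vs MDI, 2266 in OA_T0 vs OA and 392 in OA_T0 vs MDI, and the highest other split gave 0 in limma in each. Every other split mixed libraries of both groups, which puts treatment differences into the spread. The splits therefore cannot exclude chance differences between cultures.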
